A study of Mus musculus with 18 samples.

How the data were processed

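The samples were mouse embryonic stem (ES) cells of strain C57BL/6 that are deficient in HPRT, a purine salvage enzyme. Per the labels' protocols, the cells were grown on feeder cells, moved to gelatin for 1 passage, and exposed to 2.5 µM cisplatin, a platinum drug that crosslinks DNA, or to the vehicle DMSO. The exposure time is not given in the sources used here. Total RNA from 6 samples, 3 per treatment, went into 3 library types, giving 18 libraries. Samples are named below by the codes in their titles: cisplatin 8.3.3, 8.4.3 and 8.5.3, and control 8.4.16, 8.5.16 and 8.6.16.

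Per the labels' protocols, mRNA sequencing used the Illumina TruSeq mRNA kit, a kit that selects poly(A) RNA. Small RNA sequencing used the TruSeq small RNA kit. RNAome sequencing used total RNA that had been depleted of rRNA and fragmented, then ligated to small RNA adapters and sized on a gel, so that long and small RNA were read from 1 library. The 6 mRNA libraries carried 6 different indexes, and so did the 6 RNAome libraries. In small RNA sequencing the 3 cisplatin and the 3 control libraries carried the same 3 indexes, so at least 2 pools were needed. Which libraries shared a pool is not given in the sources used here, so an effect of pools on the comparison stays open.

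All values used were read counts deposited by the authors, without normalization. The submitters' processing notes name Bowtie, TopHat and edgeR, without versions or roles, and genome build mm9. The counting rule, the annotation version and the filters are not given in the sources used here. Each long RNA assay came with an expression table and an abundance table. In every library, no abundance value exceeded the expression value of the same feature, and 46.2% (mRNA) and 68.2% (RNAome) of shared features had equal values in every library. Why the tables differ is not given in the sources used here. The expression tables were used in the main tests. Genes with near-identical copies, such as histones and small nucleolar RNAs, are uncertain as single genes. Every feature of the long RNA tables had counts above 0 in at least 3 libraries.

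The long RNA tables hold RefSeq transcripts and genomic regions. Of 18943 RefSeq entries in the mRNA table, 18457 were matched to a gene symbol, and of 17787 in the RNAome table, 17337 were matched, through a RefSeq gene table of assembly GRCm38.p6 that was used for names alone. For each gene 1 transcript was kept. A transcript present in both long RNA tables was preferred, and among several the one with the highest mean scaled count (CPM) over the tables was taken, giving 14620 genes in the mRNA and 13718 in the RNAome table, including unmatched entries under their own identifiers. Regions were not used in the main tests. Of these, 28656 (mRNA) and 46857 (RNAome) coincide with introns of GENCODE vM1 on NCBIM37, the same assembly as mm9. In the small RNA tables, counts were summed per mature microRNA name and per tRNA anticodon. Entries of these tables marked as fragments were left out of the main tests and used in an alternative.

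Counts were tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test (TMM scaling, filterByExpr by group, two-sided, Benjamini-Hochberg adjusted p under 0.05). Each treatment comparison used the 6 libraries of its assay. The difference of treatment effects between assays was the interaction in a fit of 12 libraries, and levels were compared between assays in a fit of 12 libraries with treatment as covariate. A log2 fold change is given with its standard error (SE), taken as the absolute fold change divided by the square root of the F statistic. CPM values are given as mean ± SD over 3 libraries, using TMM-scaled totals of the tested features. Adjusted p-values in the text are from edgeR unless another tool is named. The designs, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except those named below as added. Nothing in the labels says that the samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

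The named long RNA genes were, per comparison, the 8 largest increases and 8 largest decreases among called genes with a log2 CPM of at least 1 and no overlap between groups, up to 4 members of each gene list with the smallest adjusted p, and Cdkn1a, Mdm2, Ccng1, Pou5f1, Nanog and Hprt. Symbols that are only clone or model numbers were counted and left unnamed. For small RNAs the numbers were 6 and 6, with a log2 CPM of at least 3.3, plus list members and miR-34a, miR-34b, miR-34c, miR-294 and miR-21. Where nothing passed, the 5 with the smallest p were named. The text gives part of the genes so named. Genes outside the rule are said to be chosen after their values were seen.

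Gene lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a table. Lists with fewer than 5 tested members have counts alone. The gene lists were p53 targets, interstrand crosslink repair, nucleotide excision repair, G1/S, G2/M, pluripotency, mesoderm and endoderm, ectoderm and epiblast, 2-cell-like state, immediate early genes, integrated stress response, NRF2 and metal response, apoptosis regulators, Nodal/BMP/Wnt targets, glycolysis and hypoxia, cholesterol synthesis, polycomb targets, feeder fibroblast markers, trophectoderm markers, polymerase III RNAs, long non-coding RNAs, replication-dependent histones, small nucleolar RNAs, ribosomal proteins and mitochondrially encoded genes. The microRNA lists were p53-linked microRNAs, the miR-290-295, miR-302/367 and miR-17-92 clusters, let-7, the Dlk1-Dio3 cluster and fibroblast microRNAs. The list of mitochondrially encoded genes had 0 members among the named genes of the tables and was not tested.

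The same sample code in 2 assays was taken as the same RNA sample, since the series design states that 6 samples were sequenced, so samples are paired across assays. The correlation of same-code deviations from the group means was 0.069 to 0.253 in long RNA and -0.098 to 0.405 in small RNA. Fits with the sample code as a block gave 0 higher and 2 lower long RNAs, and 0 and 0 small RNAs, for the interaction results. For the levels between assays they gave 4114 higher and 4416 lower long RNAs, and 177 and 180 small RNAs. The middle number of the code recurs across treatments in 2 of the pairs, with no stated meaning, and was not taken as a pairing.

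Replicates were compared before averaging. No 2 libraries of a group held identical values, and in a chi-square comparison of their counts, features with 20 or more counts differed by 1.83 to 344.2 times the sampling noise (chi-square per degree of freedom). This shows that no library repeats another, not that the samples came from separate cultures. Each library was used as 1 sample.

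The alternatives for each comparison were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter, a replicate block and each replicate left out in turn. The treatment comparisons were also run with a mean count of at least 10 and without the 10 most abundant features, and the lists with the fry test and an estimated correlation. Added after seeing the data were the abundance tables, fits without replication-dependent histones, and small RNA fits with fragments or with microRNAs alone. The fits were tested on counts simulated from the real libraries, with 200 changed genes each. For small RNAs these were 200 of 364 features in RNAome sequencing, of 587 in small RNA sequencing and of 497 in the joint fits. That share is far above the real calls of the treatment and interaction comparisons, so recovery may be overstated there. The joint fits, real and simulated, used 1 spread per feature for both assays, which the real libraries need not share. In long RNA, replicates differed by 1.83 to 5.49 times the sampling noise in mRNA and by 6.84 to 51.26 times in RNAome sequencing. A shared spread is therefore doubtful there, and recovery in the long RNA joint fits may be misstated. At a log2 change of 1 the recovered percent was 88.8 in mRNA, 57.5 in RNAome long RNA, 55.3 in RNAome small RNA, 90 in small RNA sequencing, 44 and 27 for the long and small RNA interactions, and 79.6 and 91.4 for the long and small RNA assay comparisons. At a log2 change of 2 it was 100, 100, 98.9, 100, 70.7, 90, 93 and 100 in the same order. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, rank correlations and plots.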

Results

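RNA from 6 mouse ES cell samples, 3 exposed to cisplatin and 3 to the vehicle, was sequenced in 3 ways, giving 18 libraries. Expression-table counts per library ranged from 20365963 to 31604098 in mRNA sequencing and from 43404675 to 94373096 in the long RNA table of RNAome sequencing. The small RNA tables held 1587446 to 4515956 counts per library in RNAome sequencing and 4826269 to 13428891 in small RNA sequencing. The study set a method that reads long and small RNA from 1 library beside the separate mRNA and small RNA methods, with cisplatin exposure as the condition compared.

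The libraries differed in what they held. Of the abundance-table counts, 75.9% to 77.1% lay on RefSeq protein-coding transcripts in mRNA sequencing, against 2.22% to 4.23% in RNAome sequencing, where 18.5% to 28.6% lay on RefSeq non-coding transcripts and 31.8% to 35.9% on annotated introns. The 10 most abundant features took 44.7% to 49.3% of RNAome long RNA counts and 4.0% to 4.5% of mRNA counts. MicroRNAs made up 19.1% to 38.2% of the RNAome small RNA table and 51.2% to 62.9% of the small RNA sequencing table. The counts left on tested genes in RNAome sequencing were 14634893 to 19255927 in the cisplatin libraries and 4965585, 13576126 and 6665724 in control libraries 8.4.16, 8.5.16 and 8.6.16. On the first principal component of the RNAome long RNA table (38.6% of the variance), control 8.4.16 lay at 45.86 and the other libraries between -18.57 and 3.73. In mRNA sequencing the first component (69.5%) separated the treatments.

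Hprt, the gene the cells are deficient in, was near the floor in mRNA sequencing, at 1.13 ± 0.08 CPM with cisplatin and 0.94 ± 0.18 CPM in controls (SD, n = 3 each; 41 and 34 counts; RefSeq NM_013556, chromosome X, 50341314 to 50374836 on mm9). The difference was 0.23 ± 0.31 on the log2 scale (SE, adjusted p = 0.616). Hprt was not among the genes tested in RNAome sequencing.

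The first comparison asked which poly(A) RNAs differ after cisplatin. Genes that p53, the transcription factor activated by DNA damage, is known to drive rose together in mRNA sequencing. Of 40 tested p53 targets 36 rose and 1 fell. Plk2, a kinase gene (NM_152804, chromosome 13, 111185252 to 111191052), went from 28.2 ± 5.07 to 139.7 ± 24.4 CPM (SD, n = 3 each), a log2 change of 2.31 ± 0.13 (SE). Btg2, an antiproliferative gene, rose by 2.18 ± 0.13, and Fas, a death receptor gene, by 2.80 ± 0.35. Cdkn1a (NM_007669, chromosome 17, 29227924 to 29237667), which encodes the cell cycle inhibitor p21, rose by 1.16 ± 0.09 on the log2 scale. Mdm2, the ubiquitin ligase gene that restrains p53, rose from 107.9 ± 16.3 to 263.7 ± 38.2 CPM, and Ccng1, encoding cyclin G1, from 276.3 ± 53.5 to 611.5 ± 50.1 CPM. The member that fell was Sulf2, a sulfatase gene, at -0.18 on the log2 scale, which was chosen after its value was seen. The list's median log2 change was 0.77 (camera adjusted p = 3.29e-33, and adjusted p = 0.205 with an estimated correlation). Adjusted over the list alone, 37 members rose and 1 fell.

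Genes of mitosis and of the pluripotent state fell. In the G2/M list 34 of 37 tested members fell and 1 rose, with a median of -0.38 (camera adjusted p = 1.42e-18, and adjusted p = 0.158 with an estimated correlation). Plk1, a mitotic kinase gene, fell by 0.85 ± 0.05 on the log2 scale, Ect2, a cytokinesis gene, by 0.77 ± 0.05 and the proliferation marker Mki67 by 0.57 ± 0.05. The member that rose was Aurkb, a mitotic kinase gene, at 0.17, chosen after its value was seen. Of 31 pluripotency genes 26 fell and 0 rose, by edgeR, with a median of -0.38 (camera adjusted p = 8.25e-15, and adjusted p = 0.158 with an estimated correlation). Jarid2, a polycomb cofactor gene (NM_021878, chromosome 13, 44824843 to 45017012), fell by 0.98 ± 0.06 on the log2 scale, from a mean of 679.4 to 343.9 CPM. Esrrb, a pluripotency transcription factor gene, fell by 0.61 ± 0.05 and Nanog, another, by 0.38 ± 0.06 (adjusted p = 0.00012). Pou5f1, which encodes the pluripotency factor OCT4, did not pass the test and stood at 1212 ± 35.9 CPM with cisplatin and 1211 ± 13.7 CPM in controls. Adjusted over the list alone, the counts of both lists were the same, 1 higher and 34 lower for G2/M and 0 and 26 for pluripotency.

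Further lists passed camera in mRNA sequencing. Of 30 apoptosis regulators 14 rose and 0 fell, among them Bbc3 (1.27 ± 0.13 on the log2 scale), Apaf1 (1.02 ± 0.09) and Tnfrsf10b (0.76 ± 0.09), genes of the mitochondrial and death receptor pathways (median 0.13, camera adjusted p = 0.00341, and adjusted p = 0.205 with an estimated correlation). Bbc3, Apaf1 and Tnfrsf10b are also on the p53 target list, as are Bax, Fas and Pmaip1 among the apoptosis regulators. Of 26 immediate early genes 11 rose and 2 fell (median 0.14, camera adjusted p = 0.00794, and adjusted p = 0.471 with an estimated correlation). Fosl1 and Fos, which encode subunits of the AP-1 transcription factor, rose by 2.90 ± 0.26 and 1.44 ± 0.19, while Klf6 (-0.32) and Myc (-0.24), chosen after their values were seen, fell. The integrated stress response list went the other way, with 12 of 22 members lower and 3 higher (median -0.21, camera adjusted p = 0.0045, and adjusted p = 0.729 with an estimated correlation). Atf4, the central transcription factor gene of that response, fell by 0.93 ± 0.07, its target Chac1 by 1.75 ± 0.15 and Aars, an aminoacyl-tRNA synthetase gene, by 0.44 ± 0.05, and Ddit4, an mTOR inhibitor gene, rose by 1.84 ± 0.18. Of 63 replication-dependent histones 18 fell and 0 rose by edgeR (median -0.30, camera adjusted p = 0.00185, and adjusted p = 0.893 with an estimated correlation). In the abundance table, an alternative added after seeing the data, 9 of 47 histones fell and 0 rose by edgeR (median -0.437). Adjusted over the list alone, the counts higher and lower were 14 and 0, 11 and 2, 3 and 13, and 0 and 18 in these 4 lists.

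**Figure D1:**
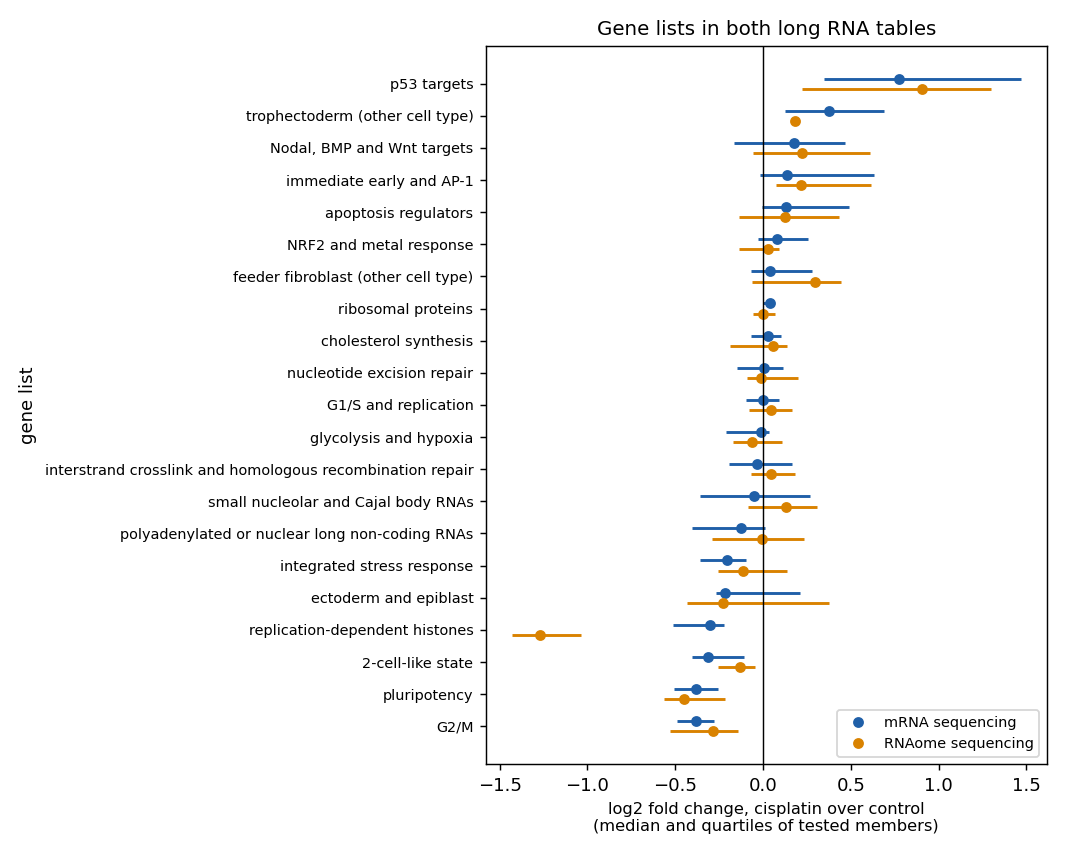
Median log2 fold change (points) and quartiles (bars) of the tested members of each gene list, cisplatin over control, in mRNA and RNAome sequencing, for lists with at least 5 tested members in both. The p53 targets lie highest, at medians of 0.77 and 0.91, and the replication-dependent histones lie at -0.30 and -1.27.

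None of the other lists that were tested passed camera in mRNA sequencing. In interstrand crosslink repair 6 of 33 members rose and 9 fell (8 and 10 adjusted over the list alone). Slx4, a nuclease scaffold gene, rose by 0.39 ± 0.06, while Fancc and Fancm of the Fanconi anemia pathway fell by 0.66 ± 0.13 and 0.33 ± 0.06. In nucleotide excision repair 3 of 24 rose and 3 fell (3 and 3 adjusted over the list alone). Ercc5, an endonuclease gene of that pathway, rose by 1.14 ± 0.07. Of 24 NRF2 and metal response genes 8 rose and 2 fell (9 and 2 adjusted over the list alone), among them the heme oxygenase gene Hmox1 (0.64 ± 0.08). The G1/S list had 3 higher and 4 lower of 30 (2 and 2 adjusted over the list alone), among them Rrm2 (0.31 ± 0.06) and Mcm6 (-0.25 ± 0.04). In glycolysis and hypoxia 1 of 27 rose and 6 fell (1 and 6), with Hk2, a hexokinase gene, at -0.80 ± 0.06. In cholesterol synthesis 1 of 22 rose and 1 fell (0 and 1), and the list's median was 0.03 while camera's direction was down (adjusted p = 0.975).

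Nodal, Lefty1 and Lefty2, which encode a TGF-beta ligand and its antagonists, rose by 0.84 ± 0.08, 0.63 ± 0.11 and 0.54 ± 0.10, while Lef1 and Axin2 of the Wnt pathway fell by 1.21 ± 0.14 and 0.72 ± 0.09. The Nodal, BMP and Wnt target list had 7 of 19 higher and 2 lower (7 and 2 adjusted over the list alone), the ectoderm and epiblast list 3 of 16 higher and 6 lower (3 and 7), and the mesoderm and endoderm list 4 of 16 higher and 2 lower (4 and 2), with Wnt3 at 2.23 ± 0.26. The 2-cell-like list had 0 of 21 higher and 3 lower by edgeR (0 and 1). Its camera adjusted p was 0.127, and 0.893 with an estimated correlation. At the preset correlation it was 0.00489, 0.0234 and 0.0381 without cisplatin 8.4.3, cisplatin 8.5.3 and control 8.5.16. Of markers of other cell types, 5 of 13 trophectoderm genes rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.116), among them Dlx3 (2.26 ± 0.35) and Ascl2 (1.02 ± 0.17), and 3 of 23 feeder fibroblast markers rose and 0 fell by edgeR (3 and 0, camera adjusted p = 0.724), namely Mmp2, Timp3 and Mmp14. The call for Mmp14 was lost without cisplatin 8.4.3 (adjusted p = 0.0589). Long non-coding RNAs had 3 of 23 higher and 7 lower (3 and 7), with Mirg of the Dlk1-Dio3 locus at -1.14 ± 0.14. Small nucleolar RNAs had 1 of 29 higher and 1 lower (0 and 0), ribosomal proteins 4 of 86 higher and 2 lower (0 and 0), and polycomb targets and polymerase III RNAs 0 of 4 and 0 of 1 called.

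Over all 13924 tested genes 2582 rose and 2688 fell. The largest increases were in genes that were low in controls, led by Rsph6a (3.63 ± 0.42 on the log2 scale, SE), which encodes a cilium component, Matn1 (3.39 ± 0.31), a cartilage matrix gene, and Insyn2a (3.34 ± 0.28). The largest decreases included the transcription factor genes Klf12 (-1.80 ± 0.17) and Gli2 (-1.46 ± 0.08), the receptor phosphatase gene Ptprg (-1.75 ± 0.09; NM_008981, chromosome 14, 12386046 to 13074555) and Tenm4 (-1.68 ± 0.14), with adjusted p between 3.33e-08 and 2.07e-06. Of 99 named genes called, 90 were called whichever 1 library was left out.

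**Figure D2:**
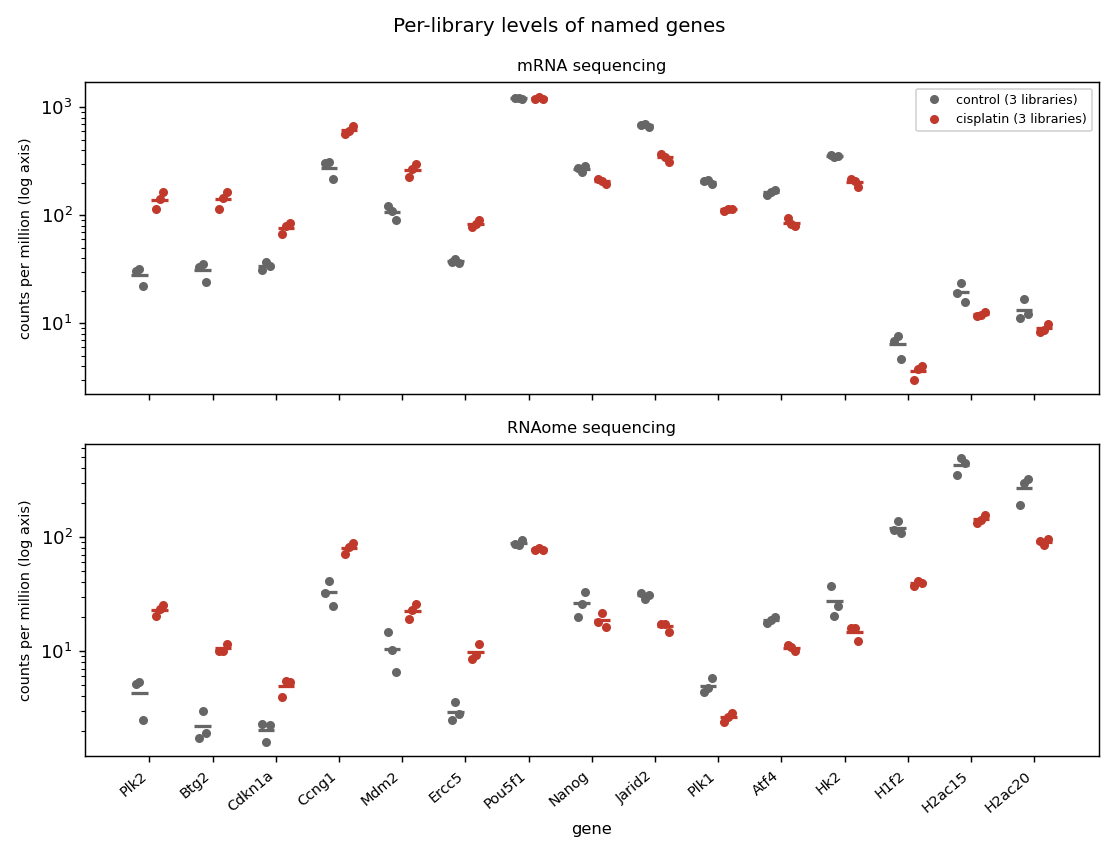
CPM of named genes in each library (points, log axis) with the group mean (line), for 3 control and 3 cisplatin libraries in mRNA sequencing (top) and RNAome sequencing (bottom). The cisplatin libraries lie above the controls for Plk2 (mean 139.7 against 28.2 CPM in mRNA and 23.1 against 4.31 CPM in RNAome sequencing) and below them for Jarid2.

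RNAome sequencing asked the same question of total RNA depleted of rRNA. The p53 targets rose here too, with 17 of 36 tested members higher and 0 lower by edgeR (22 and 0 adjusted over the list alone). Ccng1 went from 32.6 ± 7.86 to 80.3 ± 9.06 CPM (SD, n = 3 each), a log2 change of 1.29 ± 0.19 (SE), and Plk2 rose by 2.44 ± 0.23, Btg2 by 2.18 ± 0.22 and Trp53inp1, an autophagy-linked p53 target, by 1.44 ± 0.19. Cdkn1a rose by 1.30 ± 0.26 (adjusted p = 0.0075) and Mdm2 by 1.14 ± 0.22 (adjusted p = 0.00692). Without cisplatin 8.4.3 or control 8.5.16 the call for Cdkn1a was lost, and without control 8.6.16 that for Mdm2, with adjusted p up to 0.0658 and 0.062. The list's median was 0.91 (camera adjusted p = 7.58e-33, and adjusted p = 0.0479 with an estimated correlation).

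Replication-dependent histones, whose mRNAs end without a poly(A) tail, were the largest group that fell, with 56 of 67 lower and 0 higher by edgeR (66 and 0 adjusted over the list alone). The linker histone gene H1f2 (NM_015786, chromosome 13, 23830676 to 23832235) went from 120.7 ± 15.3 to 39.5 ± 1.93 CPM and H2aw, an H2A gene, from 459.5 ± 71.4 to 145.9 ± 11.3 CPM. The list's median log2 change was -1.27 (camera adjusted p = 7.28e-129, and adjusted p = 0.0937 with an estimated correlation). Histone genes have near-identical copies, so single members are uncertain and the members called may not be separate findings. For 58 members the expression counts were 1.5 times the abundance counts or more. Of the 9 others 8 were lower. The number of members lower was 27 without cisplatin 8.4.3 and 37 without cisplatin 8.3.3. Without control 8.4.16, the library that stood apart, it was 62.

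Jarid2 fell by 0.90 ± 0.16 and Spp1, which encodes osteopontin, by 0.68 ± 0.17, the 2 pluripotency-list members called of 31 (10 adjusted over the list alone, median -0.45, camera adjusted p = 2.93e-08, and adjusted p = 0.0479 with an estimated correlation). Nanog (-0.51 ± 0.18, adjusted p = 0.192) and Pou5f1 (-0.18 ± 0.16, adjusted p = 0.694) did not pass. Plk1 (-0.95 ± 0.22) and Kif23 (-0.78 ± 0.20), a cytokinesis motor gene, were the 2 called of 37 G2/M members (13 adjusted over the list alone, median -0.28, camera adjusted p = 1.41e-08, and adjusted p = 0.0937 with an estimated correlation). The call for Spp1 was lost without any 1 library other than control 8.4.16 (adjusted p up to 0.263), that for Kif23 without any 1 other than cisplatin 8.5.3 (up to 0.265), and that for Plk1 without cisplatin 8.3.3, cisplatin 8.4.3 or control 8.6.16 (up to 0.145).

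Elsewhere in RNAome sequencing, members called were Bbc3, Apaf1 and Pmaip1 of 22 apoptosis regulators (3 higher, 0 lower), Ddit4 (2.21 ± 0.25) and Atf4 (-0.80 ± 0.16) of 19 integrated stress response genes (1 and 1; 2 and 1 adjusted over the list alone), Ercc5 (1.68 ± 0.21) of 24 nucleotide excision repair genes, Nodal (1.09 ± 0.19) of 15 ectoderm and epiblast and 11 Nodal, BMP and Wnt genes, Hk2 (-0.87 ± 0.20) of 23 glycolysis genes and Slc31a1 (0.86 ± 0.20), a copper transporter gene, of 23 NRF2 and metal response genes. Bbc3, Apaf1 and Pmaip1 are all on the p53 target list too, so these calls are not separate from those of the p53 targets. The trophectoderm list had 1 of 5 members called, the keratin gene Krt19 (1.26 ± 0.31), and its call was lost without any 1 of the 6 libraries (adjusted p up to 0.22). The calls for Bbc3, Hk2, Pmaip1 and Slc31a1 were each lost without 4 or 5 of the 6 libraries taken singly, with adjusted p up to 0.151, 0.111, 0.269 and 0.131, and that for Atf4 without cisplatin 8.4.3 (0.0743). By edgeR 0 members were called of the 2-cell-like (18), cholesterol (20), feeder fibroblast (5), G1/S (30), immediate early (17), crosslink repair (31), mesoderm and endoderm (4), long non-coding (18), polycomb (1), ribosomal (84), polymerase III (8) and small nucleolar (107) lists. The ectoderm list's median was -0.23 while camera's direction was up (adjusted p = 0.706), and the excision repair list's was -0.01 with camera up (adjusted p = 0.35). The integrated stress response list's median was -0.11 and its mean 0.02, with camera down (adjusted p = 0.743).

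Adjusted over the list alone, 3 members were higher in each of the immediate early, ectoderm and epiblast, and Nodal, BMP and Wnt lists, 1 in the feeder fibroblast list, and 1 was lower in the mesoderm and endoderm list. Several lists that did not pass camera with all RNAome libraries passed without 1 of them. The 2-cell-like list did so, downward, without cisplatin 8.4.3 (adjusted p = 0.0057) or 8.5.3 (0.000565), and the apoptosis list, upward, without cisplatin 8.3.3 (0.0353). Immediate early genes passed without cisplatin 8.5.3 (0.0178), control 8.4.16 (0.00866) or control 8.6.16 (0.0394), Nodal, BMP and Wnt targets without control 8.6.16 (0.0212), and ribosomal proteins without control 8.5.16 (0.0254). Small nucleolar RNAs, with a median of 0.13 and adjusted p = 0.0905 in the test as planned, passed without cisplatin 8.3.3 (1.16e-05), cisplatin 8.4.3 (0.00606) or control 8.5.16 (6.91e-08). These left-out fits used the preset correlation of 0.01. The correlation estimated from all libraries was 0.647 for small nucleolar RNAs and 0.746 for the 2-cell-like list. With estimated correlations and all libraries, camera adjusted p was 0.5 to 0.943 for the lists just named, and 0.813 for these 2.

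In all, 97 of 9861 tested genes rose and 104 fell in RNAome sequencing. DESeq2 called 56 higher and 95 lower, 37.1% higher against 48.3% by edgeR. Without cisplatin 8.4.3 the counts were 40 and 34, without cisplatin 8.3.3 71 and 50, and without control 8.6.16 46 and 81. Without the histone genes 80 rose and 34 fell.

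Small RNA sequencing asked which microRNAs and tRNA sequences differ. miR-200b-3p, of a family known to keep epithelial identity, went from 999.4 ± 173.0 to 2832 ± 297.3 CPM (SD, n = 3 each, adjusted p = 0.000948), and miR-200a-5p rose by 1.56 ± 0.13 on the log2 scale (SE). miR-99b-5p went from 2791 ± 693.8 to 7249 ± 1160 CPM and miR-501-3p rose by 1.53 ± 0.22. Of 17 p53-linked microRNAs 5 rose and 0 fell by edgeR (8 and 0 adjusted over the list alone, median 0.42, camera adjusted p = 0.000145, and adjusted p = 0.131 with an estimated correlation), among them miR-34c-5p (0.60 ± 0.14), from 324.9 ± 20.6 to 492.3 ± 80.8 CPM, and miR-34a-5p (0.48 ± 0.12, adjusted p = 0.0439). Of 75 microRNAs of the imprinted Dlk1-Dio3 cluster 1 rose, miR-1193-3p (1.27 ± 0.18), and 7 fell (1 and 10 adjusted over the list alone, median -0.18, camera adjusted p = 7.67e-07, and adjusted p = 0.131 with an estimated correlation), among them miR-410-5p (-1.76 ± 0.27) and miR-494-5p (-2.41 ± 0.42). Both were low, miR-410-5p with 63 counts with cisplatin and 286 in controls, and miR-494-5p, near the floor, with 15 and 108.

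miR-294-3p, of the miR-290-295 cluster that ES cells express, did not pass the test in small RNA sequencing and stood at 14962 ± 242.7 CPM with cisplatin and 17105 ± 422.0 CPM in controls (adjusted p = 0.179), and miR-21a-5p, often high in fibroblasts, at -0.03 ± 0.09 on the log2 scale (adjusted p = 0.901). Of 14 members of that cluster 2 rose, miR-295-5p (0.52 ± 0.10) and miR-290-5p (0.46 ± 0.12), although the median was -0.16. The other lists had 1 of 24 fibroblast microRNAs higher (miR-145a-3p), 1 of 6 of the miR-302 cluster higher (miR-302c-3p), 1 of 27 of the miR-17-92 clusters lower (miR-92a-1-5p, 0 adjusted over the list alone) and 0 of 11 of let-7 by edgeR. The fibroblast microRNA list had a camera adjusted p of 0.3, and 0.851 with an estimated correlation. At the preset correlation it was 0.0215 and 0.0362 without cisplatin 8.3.3 and control 8.4.16.

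In total 47 of 587 small RNAs rose and 11 fell. An effect of library pools, whose layout is not given, was not tested there. Of 22 named small RNAs called, 6 were called whichever 1 library was left out, namely miR-200a-5p, miR-200b-3p, miR-99b-5p, miR-501-3p, miR-1193-3p and miR-410-5p. The calls for miR-34a-5p, miR-34b-3p and miR-34c-3p were lost without any 1 library, and that for miR-34c-5p without 4 of the 6 (adjusted p up to 0.156). The counts were 13 higher and 2 lower without control 8.4.16, 14 and 3 without control 8.6.16, 20 and 2 without cisplatin 8.5.3, 22 and 7 without cisplatin 8.3.3, 28 and 2 without cisplatin 8.4.3, and 46 and 7 without control 8.5.16.

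**Figure D3:**
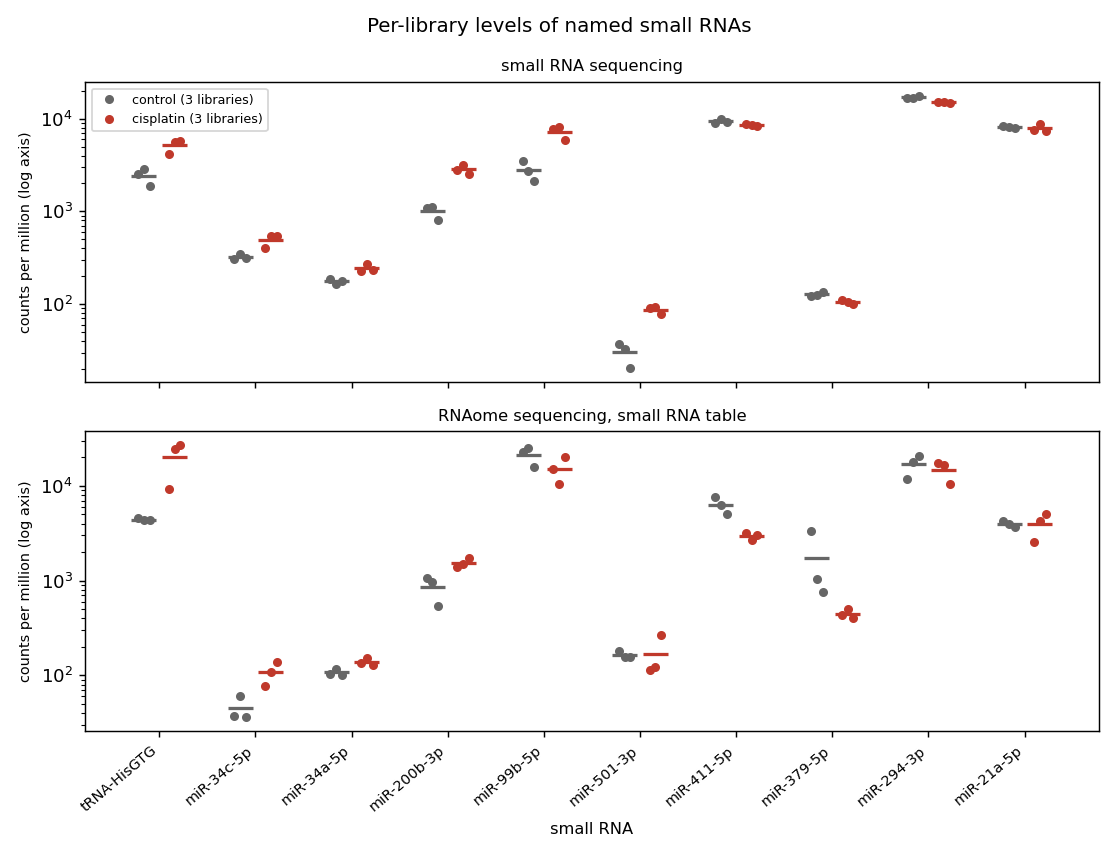
CPM of named small RNAs in each library (points, log axis) with the group mean (line), for 3 control and 3 cisplatin libraries in small RNA sequencing (top) and the small RNA table of RNAome sequencing (bottom). miR-200b-3p lies higher with cisplatin in small RNA sequencing (mean 2832 against 999.4 CPM), and miR-21a-5p overlaps between groups in both.

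In the small RNA table of RNAome sequencing 4 of 364 small RNAs rose and 1 fell. Sequences of tRNA-HisGTG, the tRNA that carries histidine, went from 4422 ± 124.5 to 20314 ± 9580 CPM (SD, n = 3 each), a log2 change of 2.20 ± 0.38 (SE, adjusted p = 0.0164). miR-1957a (1.75 ± 0.34), miR-3963 (1.74 ± 0.31) and miR-3968 (1.49 ± 0.32) rose and miR-126-5p fell by 1.44 ± 0.30. miR-34c-5p was at 1.22 ± 0.34 (adjusted p = 0.0743), and miR-379-5p and miR-411-5p of the Dlk1-Dio3 cluster were at -1.95 ± 0.48 (0.0587) and -1.10 ± 0.28 (0.0632). The Dlk1-Dio3 list had 0 of 52 members called by edgeR (7 lower adjusted over the list alone, median -0.39, camera adjusted p = 2.71e-05, and adjusted p = 0.147 with an estimated correlation), the p53-linked list 0 of 9 (1 higher adjusted over the list alone), and the let-7 (5), miR-17-92 (22), miR-290-295 (13), fibroblast (17) and miR-302 cluster (3) lists 0. The fibroblast list's median was -0.04 while camera's direction was up (adjusted p = 0.908). The call for tRNA-HisGTG was lost without cisplatin 8.4.3, cisplatin 8.5.3, control 8.4.16 or control 8.6.16 (adjusted p up to 0.0969). miR-34c-5p, miR-379-5p and miR-411-5p passed without cisplatin 8.3.3, and miR-379-5p also without control 8.5.16.

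DESeq2 called 21 small RNAs higher and 10 lower there (67.7% higher), and edgeR without a filter 16 and 8 (66.7%), against 80% in the test as planned. edgeR called 0 without cisplatin 8.4.3, cisplatin 8.5.3, control 8.4.16 or control 8.6.16, 19 higher and 10 lower without cisplatin 8.3.3, and 2 and 2 without control 8.5.16.

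Whether the treatment effect differs between methods was tested as an interaction. Among long RNAs 0 of 12919 differed by edgeR, with 754 at an unadjusted p under 0.05, and DESeq2 called 2 higher and 37 lower in RNAome sequencing. With the sample code as a block 0 were higher and 2 lower, and without control 8.4.16 2 and 24. The smallest p-values were for Slc31a1 (0.89 ± 0.18 on the log2 scale, RNAome minus mRNA, adjusted p = 0.268), Adgra3 (0.84 ± 0.17, 0.268), Arpp19 (0.72 ± 0.16, 0.43), Cd276 (-1.09 ± 0.25, 0.43) and the histone gene H2aj (-1.01 ± 0.23, 0.43). The replication-dependent histones had a median of -0.90, with 0 of 63 called over all genes and 56 lower adjusted over the list alone. In the other lists 0 were called, and 1 NRF2 and metal response member and 1 of 2 polymerase III RNAs were higher adjusted over the list alone.

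Among small RNAs 6 of 497 had a higher and 4 a lower treatment effect in RNAome than in small RNA sequencing, with 0 and 0 when the sample code was a block (edgeR, 85 at an unadjusted p under 0.05 without the block, and DESeq2 19 and 12 without it). miR-411-3p (2.76 ± 0.56) and miR-1957a (1.87 ± 0.38) were higher and miR-1197-3p (-2.65 ± 0.49) and miR-99b-5p (-1.83 ± 0.38) lower, each with adjusted p = 0.0253. In RNAome sequencing miR-411-3p had only 19 counts with cisplatin and 3 in controls, and miR-1197-3p 3 and 21, so both were near the floor. The RNAome mean of miR-99b-5p was lower with cisplatin, at 20676 ± 6070 against 28568 ± 7260 CPM (SD), opposite to its rise in small RNA sequencing. In fits without 1 sample the counts were 0 to 1 higher and 0 to 2 lower. Of 69 Dlk1-Dio3 microRNAs 1 was higher and 2 lower (1 and 4 adjusted over the list alone), and in the other microRNA lists 0 were called.

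The log2 fold changes of the 2 long RNA methods had a Pearson r of 0.699 and a Spearman rho of 0.626 across 9718 genes, which are not independent replicates. Of the 97 genes higher in RNAome sequencing 95 were also higher in mRNA sequencing, against 13.9 for independent lists, and of 99 lower 63, against 25.2, with 0 called in opposite directions. The same RNA samples are behind both, so part of this comes from shared samples. Other splits of the 6 samples gave r up to 0.419 and a covariance up to 0.0216, against 0.101 for the real split. With different samples behind the fold changes the median r over 18 choices was 0.504 (0.372 to 0.596), against 0.539 with shared samples and equal numbers. For 360 small RNAs r was 0.222 and rho 0.253, other splits gave r up to 0.210 and a covariance up to 0.0406 against 0.0604, and the median r with different samples was 0.152 (-0.025 to 0.378). Of 4 small RNAs higher in RNAome sequencing 2 were higher in both tables, against 0.344 for independent lists.

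Levels were also compared between methods. Small nucleolar RNAs and histones, RNAs without a poly(A) tail, made the largest gap. All 45 small nucleolar RNAs and all 63 replication-dependent histones tested were higher in RNAome sequencing, with median log2 differences of 9.74 and 8.70. Snord83b had 9 counts with cisplatin and 18 in controls in mRNA sequencing, against 2198248 and 787758 in RNAome sequencing, and Rmrp, the RNA of an RNA-processing ribonuclease, was higher by 13.44 ± 0.37 (SE, n = 6 libraries each). Rian and Kcnq1ot1, imprinted long non-coding RNAs, were higher by 6.12 ± 0.24 and 4.19 ± 0.14, and 16 of 22 long non-coding RNAs were higher and 1 lower. Rpl29 (-4.75 ± 0.26), a ribosomal protein gene, Laptm5 (-4.22 ± 0.22) and Zyx (-3.93 ± 0.25), an adhesion gene, were lower in RNAome sequencing. The pluripotency genes Klf4 (-2.56 ± 0.12) and Utf1 (-2.49 ± 0.14) were lower and Pou5f1 (-0.18, adjusted p = 0.0718) did not pass. In all 4180 of 12919 genes were higher and 4449 lower.

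Members called higher and lower in the other lists were 16 and 14 of 40 p53 targets, 24 and 8 of 37 G2/M genes, 10 and 16 of 30 G1/S genes, 13 and 0 of 20 2-cell-like genes, 38 and 36 of 86 ribosomal protein genes and 1 and 9 of 17 feeder fibroblast markers. Between the small RNA methods 181 of 497 small RNAs were higher in RNAome sequencing and 183 lower. miR-6236 (7.60 ± 0.38) and miR-5117-5p (6.68 ± 0.35) were higher and miR-411-3p (-5.62 ± 0.33) and miR-674-5p (-4.72 ± 0.25) lower. In small RNA sequencing miR-6236 had only 15 counts with cisplatin and 29 in controls, and miR-5117-5p 30 and 44. In RNAome sequencing miR-411-3p had 19 and 3, and miR-674-5p 6 and 3. The sizes of these differences thus rest on values near the floor in 1 method. miR-294-3p was higher by 0.85 ± 0.16 and miR-34c-5p lower by 1.63 ± 0.20. Of Dlk1-Dio3 microRNAs 16 were higher and 30 lower of 69, and of fibroblast microRNAs 6 and 11 of 20. These differences include the chemistry of each library type.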

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

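The tests below that were chosen only after the result was seen are those of gene span in RNAome sequencing, of elongation, of a rise of all tRNA sequences, of library pools, of reads counted at several copies and of S phase. The tests of transcript length, GC content, genomic DNA background, tRNA scaling, the divergent control library and other splits of the samples were set before their results were seen.

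Values outside the main measurement differed with treatment in several parts of the tables (edgeR, adjusted p under 0.05). Regions outside annotated introns had 552 higher and 598 lower of 8155 in mRNA sequencing and 25 and 38 of 4468 in RNAome sequencing (DESeq2 240 and 358, and 18 and 27). Fragment entries of the small RNA tables had 12 higher and 4 lower of 3639 in small RNA sequencing and 1 and 10 of 5968 in RNAome sequencing (DESeq2 67 and 45, and 15 and 97). Introns summed per gene had 662 higher and 577 lower of 8342 in mRNA sequencing and 58 and 22 of 5845 in RNAome sequencing (DESeq2 299 and 218, and 14 and 4).

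The treatment effect differed between RNAome and small RNA sequencing for 10 microRNAs by the interaction test. The log2 differences, RNAome minus small RNA sequencing, were 3.21 for miR-1195 (outside the rule, chosen after its value was seen), 2.76 for miR-411-3p, 1.87 for miR-1957a, 1.596 for miR-322-3p, 1.23 for miR-3963, 1.23 for miR-3096b-5p, -1.18 for miR-379-3p, -1.50 for miR-126-5p, -1.83 for miR-99b-5p and -2.65 for miR-1197-3p. The RNAome values of miR-411-3p and miR-1197-3p rested on few counts, 19 and 3 with cisplatin and 3 and 21 in controls. With the sample code as a block 0 passed.

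Long genes were lower with cisplatin in mRNA sequencing, with a Spearman correlation of log2 fold change with gene span of -0.322 over 13045 genes, and 152 of 239 genes over 300 kb fell and 8 rose, against 247 and 735 of 3447 under 10 kb. Given transcript length or GC content, the partial correlations were -0.276 and -0.255, so neither alone accounts for the whole of it. Both together were not tested. The log2 fold change correlated with GC content itself at 0.332 in mRNA and 0.122 in RNAome sequencing (Spearman), so a part through GC content stays open. 3' bias of poly(A) selection is argued against by a correlation with gene span of -0.217 in RNAome sequencing. A candidate explanation is slower or incomplete elongation. In RNAome sequencing the log2 ratio of intron reads 100 kb or more from the gene start to those within 50 kb was lower with cisplatin, at -0.124 in genes over 100 kb (3 against 3, exact p = 0.1, the smallest possible), -0.172 after subtracting intergenic reads as genomic DNA background, and -0.342 in genes over 300 kb, but it overlapped between groups in genes of 100 to 300 kb (-0.095), while in mRNA sequencing it was lower over 100 kb (-0.148) and at 100 to 300 kb (-0.214) and overlapped over 300 kb (0.004). By distance from the gene start (under 20, 20 to 50, 50 to 100, 100 to 200 and over 200 kb) the difference was 0.031, 0.006, -0.109, -0.064 and -0.190 in RNAome and -0.068, -0.025, -0.095, -0.190 and -0.178 in mRNA sequencing, not a steady fall, and of genes with at least 20 counts in each part and group 172 of 245 and 147 of 207 had a lower ratio, so elongation stays open.

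Sequences of tRNA-HisGTG were higher with cisplatin in both small RNA tables, by 2.20 ± 0.38 in RNAome and 1.10 ± 0.17 in small RNA sequencing (SE, adjusted p = 0.0164 and 0.00632). Other anticodons were also mostly above 0 (30 of 45 and 39 of 43), but with medians of 0.399 and 0.358 and upper quartiles of 0.913 and 0.538, the latter narrowly under 0.5 of the 1.10, so a rise of all tRNA sequences does not account for the whole of it. Pools of small RNA sequencing do not account for the 2.20 seen in RNAome libraries with 6 different indexes, and scaling does not, since its share of tRNA counts was higher in all 3 cisplatin libraries in 2 of 2 tables (13.5% ± 3.75 against 5.81% ± 0.90, and 8.35% ± 1.56 against 4.92% ± 0.89, exact p = 0.1 each, the smallest possible). The RNAome call was lost without cisplatin 8.4.3, cisplatin 8.5.3, control 8.4.16 or control 8.6.16 (edgeR adjusted p up to 0.0969). It was also lost when fragment entries were fitted together with the other small RNAs, where 0 of the planned RNAome calls were kept. As a hypothesis, processing or stability of this tRNA may differ after cisplatin, which was not tested.

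Replication-dependent histones were lower with cisplatin in RNAome sequencing, with a median of -1.27. The divergent control library 8.4.16 does not account for it, since the median without it was -1.512. The 9 members whose expression and abundance counts differed by less than 1.5 times had a median of -1.177, with 8 lower. All members had -1.249 in the abundance table. The fall was thus not confined to members whose expression and abundance counts differ more. Since the rule behind these counts is not given, reads counted at several copies cannot be excluded. Fewer cells in S phase may still explain it, because the G1/S list had 4 members lower and 3 higher in mRNA sequencing (exact binomial p = 1), which decides nothing. The medians without 1 library lay between -1.058 and -1.512, with 27 members lower without cisplatin 8.4.3 and 37 without cisplatin 8.3.3, against 56.

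For each treatment comparison the 6 samples have 10 splits, too few for a share under 0.05. The real split gave 5270 calls in mRNA sequencing, 201 in RNAome long RNA, 5 in RNAome small RNA, 58 in small RNA sequencing and 10 in the small RNA interaction, in each of which 1 split, the real one, was as large and the highest other gave 0. The long RNA interaction had 0 calls in all 10 splits by edgeR (DESeq2 2 and 37 for the real one). Lists passing camera numbered 7 in mRNA sequencing (highest other split 11, and 7 splits as large), 4 in RNAome long RNA (8, and 9 splits), 1 in RNAome small RNA (2, and 5 splits) and 2 in small RNA sequencing (4, and 6 splits), so the number of lists past the preset correlation is not by itself a sign of treatment. The correlation between long RNA methods was 0.699 (highest other 0.419) and between small RNA methods 0.222 (0.210). For levels between methods 60 of 462 splits were drawn, and 1 of them, the real one, was as large in each, with 8629 long RNA calls (highest other 3895) and 364 small RNA calls (66). Most of these splits leave the 2 libraries of some sample together. Of the 32 splits that part every such pair, 1, the real one, was as large in each, and the highest other gave 3316 and 2 calls.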

How the results depend on the processing

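The abundance tables, fits without histones, fragment entries and microRNAs alone were alternatives chosen after seeing the data. In mRNA sequencing and in the comparisons of levels between methods the counts of genes called higher and lower over the whole table stayed within 1.5 times its planned value under the alternatives run. Named genes were compared under DESeq2 size factors, the DESeq2 test, the replicate blocks and each replicate left out. Lists were compared under those size factors, the block by the middle number of the code, each replicate left out, fry and an estimated correlation. No named value or list that was called changed sign in these alternatives. Of these results, 5458 kept their side of the threshold, 285 lost a call, 70 gained one and 102 changed sign without passing the test. Named genes and lists were not compared in this way under the other alternatives.

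The following counts differed more, and the cause was not tested. For RNAome long RNA, DESeq2 gave 56 higher, the replicate block by the middle number of the code 57 higher, leaving out 1 library 40 to 93 higher and 34 to 125 lower, and removing the histone genes 34 lower. For RNAome small RNA, DESeq2 gave 21 higher and 10 lower, no filter 16 and 8, that block 0 and 0 (edgeR, 68 at an unadjusted p under 0.05), leaving out 1 library 0 to 19 and 0 to 10, a fit of fragment entries together with the other small RNAs 1 and 10, and microRNAs alone 5 lower. The 1 and 10 of the fit with fragment entries were all fragment entries, and 0 of the planned calls were kept there. For small RNA sequencing, the block by the middle number gave 20 lower, leaving out the 10 most abundant features 28 higher, leaving out 1 library 13 to 46 higher and 2 to 7 lower, a fit of fragment entries together with the other small RNAs 16 and 4, and microRNAs alone 29 and 4. Of the 16 and 4 in the fit with fragment entries, 12 and 4 were fragment entries, and only 4 of the 58 planned calls were kept. For the long RNA interaction, DESeq2 gave 2 higher and 37 lower, with most adjusted p-values left undefined by it, the sample-code block 2 lower, and leaving out 1 sample 0 to 2 higher and 0 to 24 lower, the highest without control 8.4.16. For the small RNA interaction, DESeq2 gave 19 and 12, the sample-code block 0 and 0, and leaving out 1 sample 0 to 1 and 0 to 2.

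With an estimated correlation camera passed 0 lists in mRNA sequencing, 2 in RNAome long RNA, 0 in RNAome small RNA and 0 in small RNA sequencing, and fry passed 12 in mRNA sequencing. The correlation between long RNA methods was 0.741 with a mean count of at least 50, 0.620 to 0.682 leaving out 1 sample and 0.504 with disjoint libraries. That between small RNA methods was 0.166 to 0.329 leaving out 1 sample. With the block by the middle number the immediate early list in mRNA sequencing did not pass camera at the preset correlation (adjusted p = 0.0666). That number is shared by 2 pairs of samples with correlations of deviations from -0.118 to 0.446 over the 4 tables, a hint at most, and the block gave 3101 higher and 3291 lower in mRNA sequencing. The other samples stand alone in their block, so only these 2 pairs inform the treatment effect there. Little is left to estimate the spread from, so all results with this block are weak as checks. The sample-code block moved no count of the level comparisons by more than 1.5 times. Planned pseudocount alternatives were not run, since the files hold counts. Of simulated RNAome genes with a log2 change of 1, 57.5% of long and 55.3% of small RNAs were found. The small RNA simulation changed 200 of 364 features, against 5 called in the real data, so its percent may be too high.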

Other observations

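All values in this part were chosen after they were seen. Summed over introns, Mdm2 rose by 1.61 ± 0.11 on the log2 scale (SE, n = 3 per group) in mRNA sequencing and by 1.87 ± 0.21 in RNAome sequencing, and the transporter gene Abcb1b by 1.504 and 1.403. Ptp4a3, a phosphatase gene, rose by 1.91 ± 0.13 and Trp53inp1 by 1.68 ± 0.13 in mRNA sequencing. Klf12 introns fell by 1.87 and 1.83. All passed edgeR at an adjusted p under 0.05.

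Regions outside annotated introns also differed (mm9, edgeR). In RNAome sequencing a region on chromosome 2 from 111997165 to 112079997 rose by 3.02 ± 0.44 (SE). It overlaps Lpcat4, a phospholipid acyltransferase gene. A region on chromosome 12 from 110966413 to 110971980, between the coding genes Rtl1 and Dio3 and over the microRNA genes Mir382 and Mir544, fell by 1.71 ± 0.22 (adjusted p = 0.00213). Regions on chromosome 13 beside histone genes fell as well, such as 23837391 to 23838602, which overlaps H3c3, at -1.65 ± 0.20.

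The most abundant tRNA-HisGTG sequence in RNAome sequencing was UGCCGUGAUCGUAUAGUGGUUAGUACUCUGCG, with 37.1% of that tRNA's counts (22260 counts). In small RNA sequencing it was the shorter UAGUGGUUAGUACUCUGCG, with 17.5% (22601 counts).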
